A study of Arabidopsis thaliana with 6 samples.

How the data were processed

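Whole Arabidopsis seedlings were grown on MS medium with 0.8% sucrose under 16 h of light and 8 h of dark and collected at ZT12, per the labels. Total RNA was extracted with TRIzol, treated with DNase I, and 500 ng went through a poly(A) selection module, per the labels' protocols. Col-0, lhp1-3 and importin123 had 2 libraries each, grouped by title.

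The authors deposited 1 table with a count and an RPKM value for each of 34262 features in each of the 6 libraries. FastQC, HISAT2, SAMtools, bedtools and edgeR are named, with the TAIR10 build, per the submitters' processing notes. Their versions, settings and use of strand are not given in the sources used here. The deposited counts were whole numbers and were used as they stood. The RPKM values of the authors were per kb of the whole gene span and per total of each column, and were used for limma, for describing silent genes and for filters. Counting over the span takes in intron reads, and reads in overlapping genes or near-identical copies can be misplaced.

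The 2 libraries per genotype, more than depth (70137900 to 95101900 counts), limited the precision. Replicates correlated across features at 0.986, 0.992 and 0.990 (Pearson, log2 CPM), and a chi-square test per degree of freedom gave 29.9, 22.0 and 52.8, so no pair was 1 library deposited more than once. Of the features, 32548 matched the gene table of assembly TAIR10.1, which was used for symbols, biotypes, gene structure and neighbours, and no coordinate is printed. There were 133 chloroplast, 152 mitochondrial and 1429 other features, and 24 features had no count.

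The tests fixed before the data were examined used edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and the robust quasi-likelihood test on all 6 libraries, with 1 coefficient per genotype, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. This tested 33906 features, with a common biological coefficient of variation of 0.140. Every adjusted p of a gene comes from this test, on deposited or subtracted counts, unless another tool is named. SE was the absolute log2 fold change divided by the square root of F. The 20 gene lists, 357 genes of which 356 were in the file, were also fixed before. They covered importin alpha, Polycomb, floral MADS-box, flowering-time, meristem, triterpene, seed, jasmonate, ABA and cold, flavonoid, glucosinolate, salicylic acid, heat-shock, touch, clock, auxin, photosynthesis, root, anther and reference genes. Lists with at least 5 tested members went through camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists and the 3 comparisons. Overlaps were set beside independent lists, a one-sided Fisher's exact test and 20 simulated sets of unchanged groups sharing the Col-0 libraries.

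After the data were seen, a floor was subtracted. The floor of a library was its median reads per kb over 2300 silent genes, the lowest 10% of protein-coding nuclear genes of at least 1000 bp, times each gene's length. Nuclear genes were kept that stood at least as far above the floor as the floor itself, with a mean of at least 10 counts, over all 6 libraries, so a gene silent in some genotypes entered only where it was high in another. In a first version 179 genes matching an organelle genome over at least 100 bp at 95% identity or more (BLAST 2.17.0) were kept, and they were then left out. This left 19691 genes, of which 19689 were tested, with a coefficient of variation of 0.142. Apart from reversed values, a subtracted fold is printed only where both genotypes stood above the floor by at least 0.5 of it.

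Named genes followed a rule fixed before. It took LHP1 and the 9 importin alpha genes, the 8 largest rises and falls per mutant with an adjusted p under 0.05, at least 1 CPM in the higher genotype, both mutant libraries beyond both Col-0 libraries and a symbol, up to 4 members per list and direction with the smallest adjusted p, and other list members with their values. It took the 5 largest rises and falls between the mutants and the 6 largest changes shared by both. The rule was applied to deposited and to subtracted counts. Other members were picked with their values in view.

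Alternatives fixed before were RLE size factors, DESeq2 1.42.0, the legacy edgeR test, only the 4 libraries compared, the replicate number as a block, each library left out, no filter, a mean of at least 20 counts, a 2-fold minimum, limma-trend on log2(RPKM + 1) with a mean RPKM of at least 0.5, fry, an estimated correlation, and each mutant against a different Col-0 library. Nuclear genes only, a mean RPKM of at least 10, and a floor changed by 25% were added later. The fits, most alternatives, list tests and calls shared by both mutants were tested on simulated data. With a floor of the form then subtracted added to the mutant libraries, 17475 and 18087 unchanged genes were called in lhp1-3 and importin123 (33624 and 33614 tested), and 21 and 16 after subtraction (19425 and 19418 tested). This cannot show how well the real floor was removed. Subtraction recovered 96.9% and 90.6% of 4-fold, 67.7% and 68.2% of 2-fold, and 13.4% and 27.4% of 1.5-fold changes. Python 3.11.15, matplotlib 3.10.9 and pysam 0.24.0 (gene structure) were used.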

Results

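Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings collected at ZT12, 12 h after dawn. The genotypes were the wild type Col-0, lhp1-3, which carries a mutation in LHP1 (LIKE HETEROCHROMATIN PROTEIN1, a reader of Polycomb-marked chromatin), and importin123, a triple mutant in genes of importin alpha, the adaptor that carries cargo into the nucleus. Each genotype had 2 libraries, 6 in all. Total counts, to 6 significant digits, were 78775100 and 95101900 in Col-0, 90725000 and 81566900 in lhp1-3, and 70137900 and 71527800 in importin123. The study asked, by its title, how far the genes misregulated in the 2 mutants overlap. Nothing in the labels says that the libraries came from separate plantings, so p-values measure the spread between these samples, which may be technical.

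The mutant libraries carried reads on genes that were nearly silent in Col-0. Over the 2300 protein-coding nuclear genes of lowest level, the median RPKM was 0.207 and 0.249 in Col-0, 1.53 and 1.45 in lhp1-3, and 1.79 and 1.32 in importin123 (0.228 ± 0.0298, 1.49 ± 0.0584 and 1.56 ± 0.329, mean ± SD, n = 2). This floor, spread over gene length, amounted to 1.47% and 1.77% of nuclear counts in Col-0, 12.5% and 11.7% in lhp1-3, and 15.4% and 10.6% in importin123. Chloroplast features took 2.95% and 3.27% of counts in Col-0, 14.9% and 14.5% in lhp1-3, and 18.7% and 13.7% in importin123. Each genotype therefore is described on the counts as deposited, which was the test fixed before the data were examined, and after subtracting each library's floor, which was chosen after seeing the data. Pairs of log2 fold changes are given ± SE in that order, each from 2 libraries per genotype. Where a gene lay too near the floor in either genotype after subtraction, only the deposited value is given. Where leaving out 1 library ended a call or moved a printed value by over 1.5 times, the value without it is given in parentheses, or near the floor the adjusted p of a lost call.

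**Figure D1:**
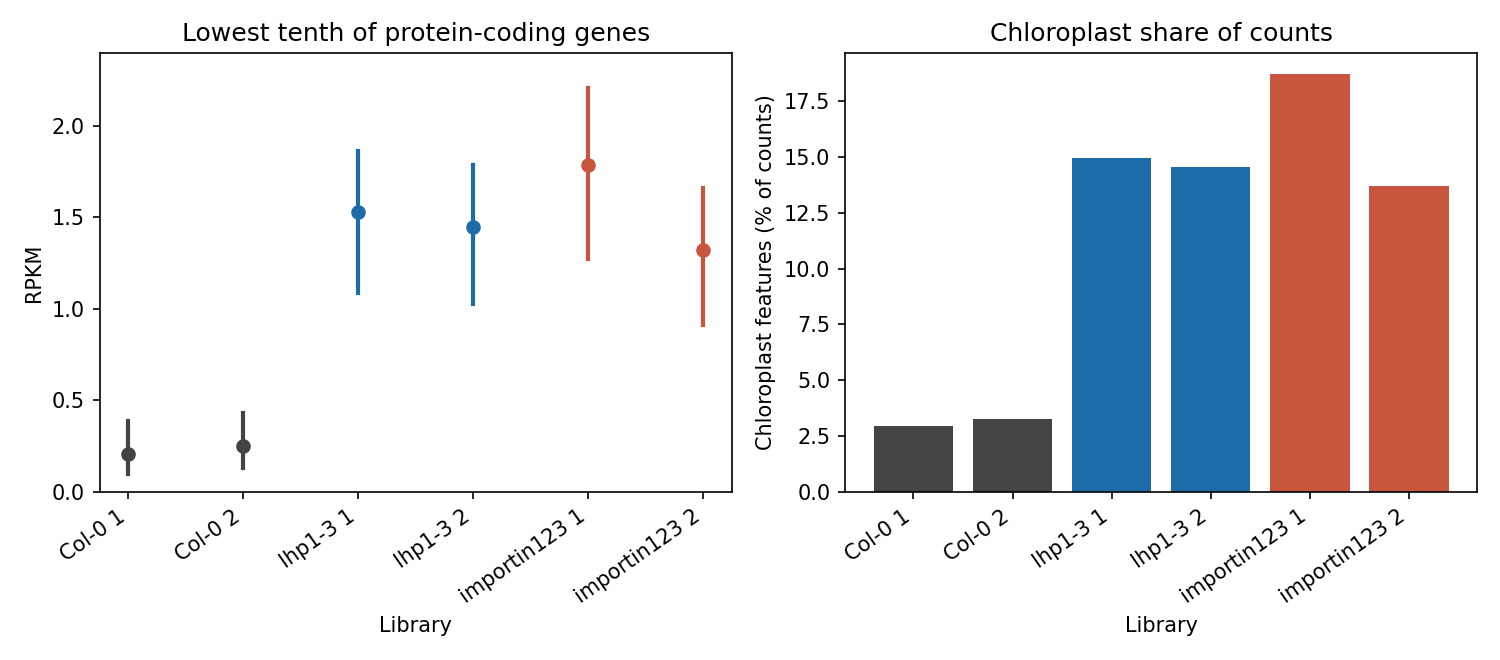
Floor of reads in each of the 6 libraries, as the RPKM of the 2300 nuclear genes of lowest level (dots, medians; bars, 5th to 95th percentile of these genes) and as the chloroplast share of all counts in percent. The medians were 0.207 and 0.249 in Col-0 and 1.32 to 1.79 in the 4 mutant libraries.

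The mutated genes were lower in the libraries labelled with them. LHP1 stood at 17.7 and 17 CPM in Col-0, 9.1 and 7.95 in lhp1-3, and 12.9 and 14.2 in importin123. LHP1 (AT5G17690, -1.03 ± 0.13 and -1.02 ± 0.15) fell in lhp1-3. In importin123 the same gene stood at -0.36 ± 0.12, a deposited call, and at 0.04 ± 0.15 after subtraction (adjusted p = 0.83). IMPA1 stood at 112 and 110 CPM in Col-0, 61.3 and 62.9 in lhp1-3, and 11.2 and 10.4 in importin123. For IMPA2 the values were 151 and 145, 73.1 and 86.1, and 7.27 and 6.6 CPM, and for IMPA3 they were 43.7 and 41.4, 27.7 and 25, and 11.1 and 10.6 CPM. In importin123, IMPA1 (AT3G06720, -3.36 ± 0.14 and -3.51 ± 0.10) and IMPA3 (AT4G02150, -1.97 ± 0.12 and -1.87 ± 0.12) fell, and IMPA2 (AT4G16143, -4.41 ± 0.17) fell to the floor. In lhp1-3, IMPA1 (-0.84 ± 0.13 and -0.23 ± 0.09), IMPA2 (-0.89 ± 0.14 and -0.25 ± 0.11) and IMPA3 (-0.69 ± 0.12 and -0.19 ± 0.11) fell on the deposited counts but did not pass after subtraction (adjusted p = 0.115, 0.167 and 0.267). Whether the reads left on a mutated gene cover the mutated part was not analysed here. LHP1 (-0.33, -0.28 and -0.18) lost the deposited call in importin123 without Col-0 replicate 1, lhp1-3 replicate 1 or importin123 replicate 1. Of the other importin alpha genes, IMPA5 (AT5G49310, 2.2 ± 0.26), IMPA7 (AT3G05720, 2.2 ± 0.25) and IMPA8 (AT5G52000, 2.21 ± 0.27) lay at the floor, where their deposited rises in lhp1-3 were matched in importin123 (2.15 ± 0.26, 2.05 ± 0.25 and 1.96 ± 0.27). IMPA4 (AT1G09270, -0.63 ± 0.13 and -0.04 ± 0.10) fell as deposited in lhp1-3 and passed no test after subtraction, while IMPA6 (AT1G02690, -0.26 ± 0.12 and 0.11 ± 0.14) passed neither and IMPA9 (AT5G03070, -0.29 ± 0.12 and -0.24 ± 0.14) passed as deposited alone. In importin123, IMPA4 (-0.55 ± 0.13 and 0.11 ± 0.10) fell as deposited alone, and IMPA6 (-0.13 ± 0.12 and 0.36 ± 0.14) and IMPA9 (-0.10 ± 0.12 and 0.14 ± 0.14) passed neither test. IMPA4 (-0.51) lost the deposited call in lhp1-3 without lhp1-3 replicate 1. IMPA9 (-0.26, -0.32, -0.20, -0.34, -0.24 and -0.24) lost the deposited call in lhp1-3 without each of the 6 libraries in turn. In lhp1-3, of 9 importin alpha genes, 3 rose and 5 fell as deposited, and 0 and 0 of 6 after subtraction (3 and 6, then 0 and 0, adjusted over the list alone, camera adjusted p = 0.416 and 0.276, subtracted counts of 0 and 1 at an unadjusted p under 0.05 and 0 and 0 in DESeq2, deposited median -0.29, mean 0.33 and test pointing down). In importin123, of 9 importin alpha genes, 3 rose and 4 fell as deposited, and 0 and 3 of 6 after subtraction (3 and 4, then 0 and 3, adjusted over the list alone, camera adjusted p = 0.301 and 0.0851).

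The first comparison was lhp1-3 against Col-0. In lhp1-3, named floral genes rose and named seed storage genes fell. The MADS-box genes SEP3 (AT1G24260, 4.43 ± 0.33 and 5.66 ± 0.45), SEP1 (AT5G15800, 4.33 ± 0.15 and 6.03 ± 0.32), PI (AT5G20240, 3.03 ± 0.18 and 4.28 ± 0.25), SEP4 (AT2G03710, 0.88 ± 0.13 and 1.37 ± 0.19) and FUL (AT5G60910, 1.72 ± 0.28 and 2.19 ± 0.35) rose, and SEP2 (AT3G02310, 4.16 ± 0.26), AP3 (AT3G54340, 4.0 ± 0.24) and AG (AT4G18960, 3.03 ± 0.18) rose from the floor of Col-0. SEP3 went from 2.06 ± 1.01 to 44.9 ± 1.05 CPM (SD, n = 2). The florigen gene FT (AT1G65480, 1.63 ± 0.15 and 2.28 ± 0.35) rose, from 8.65 ± 0.737 to 26.7 ± 4.34 CPM, as did the floral promoters AGL24 (AT4G24540, 1.09 ± 0.15 and 1.52 ± 0.18), SPL4 (AT1G53160, 2.1 ± 0.29 and 2.74 ± 0.52) and SPL3 (AT2G33810, 0.57 ± 0.20 and 0.96 ± 0.22). The floral repressors SVP (AT2G22540, -1.25 ± 0.15 and -0.74 ± 0.12), SMZ (AT3G54990, -1.22 ± 0.13 and -1.37 ± 0.17) and TEM2 (AT1G68840, -1.58 ± 0.19 and -0.88 ± 0.16) fell, whereas the repressor FLC (AT5G10140, 0.82 ± 0.16) was not among the genes testable after subtraction. Regulators of meristems and organ boundaries rose too, namely the homeobox genes KNAT1 (AT4G08150, 0.75 ± 0.15 and 1.08 ± 0.24), KNAT6 (AT1G23380, 0.69 ± 0.13 and 0.68 ± 0.16) and RPL (AT5G02030, 0.44 ± 0.13 and 1.01 ± 0.13) and the boundary gene LOB (AT5G63090, 0.87 ± 0.16 and 1.16 ± 0.21). Of 15 floral MADS-box genes, 15 rose and 0 fell as deposited, and 6 and 0 of 6 after subtraction (15 and 0, then 6 and 0, adjusted over the list alone, camera adjusted p = 2.72e-05 as deposited, adjusted p = 0.868 with an estimated correlation). PI, SEP3, SEP1, AP3 and FUL entered the subtracted count through their lhp1-3 level, and SEP4 alone passed without it. The floor may add to the deposited rises, as 12 of 15 also rose in importin123. Of 27 flowering-time genes, 15 rose and 5 fell as deposited, and 5 and 4 of 16 after subtraction (16 and 5, then 5 and 5, adjusted over the list alone, camera adjusted p = 0.294 and 0.732, subtracted median -0.02, mean 0.24 and test pointing up). Of 19 meristem and boundary genes, 14 rose and 2 fell as deposited, and 4 and 0 of 7 after subtraction (14 and 2, then 5 and 0, adjusted over the list alone, camera adjusted p = 0.0582 and 0.0075, adjusted p = 0.868 and 0.55 with an estimated correlation). SEP1 and SEP2 are close copies whose reads may be shared. SPL3 (0.47, 0.62 and 0.56) lost the deposited call without Col-0 replicate 1 or lhp1-3 replicate 1 or 2. RPL (0.32) lost the deposited call without lhp1-3 replicate 2. SEP3 (5.05) shifted as deposited without Col-0 replicate 2. FUL (2.03), SPL4 (2.36), SVP (-0.71), TEM2 (-0.71), LOB (1.05), FT (2.08) and KNAT1 (0.68) lost the subtracted calls without lhp1-3 replicate 1. FT (2.17) and KNAT1 (1.08) lost the subtracted calls without Col-0 replicate 2. SPL3 (0.88, 1.06, 0.99 and 0.95) and KNAT6 (0.59, 0.77, 0.71 and 0.65) lost the subtracted calls without each Col-0 or lhp1-3 library in turn. SEP3 (6.62) and FUL (2.85) shifted after subtraction without Col-0 replicate 2. SEP1 (6.66) shifted after subtraction without Col-0 replicate 1.

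Named genes of seed reserves, jasmonate synthesis, cold response and pigments fell in lhp1-3. The seed storage globulin genes CRU3 (AT4G28520, -4.34 ± 0.50 and -4.25 ± 0.38) and CRA1 (AT5G44120, -3.62 ± 0.24 and -3.08 ± 0.20) fell, and so did the oil body genes OLEO1 (AT4G25140, -2.31 ± 0.13 and -2.02 ± 0.11) and OLEO2 (AT5G40420, -2.22 ± 0.15 and -1.76 ± 0.17) and the peroxiredoxin gene PER1 (AT1G48130, -1.76 ± 0.15 and -1.27 ± 0.16). CRU3 went from 173 ± 55.9 to 8.51 ± 0.341 CPM (SD, n = 2). ABI5 (AT2G36270, 0.65 ± 0.15), a seed transcription factor gene, rose as deposited and had a subtracted value of 0.70 ± 0.20 (adjusted p = 0.0499). Enzyme genes of jasmonate synthesis, AOC1 (AT3G25760, -2.56 ± 0.23 and -2.34 ± 0.18), AOC2 (AT3G25770, -2.38 ± 0.21 and -1.76 ± 0.17) and AOS (AT5G42650, -2.18 ± 0.19 and -1.54 ± 0.16), fell, while the storage protein gene VSP1 (AT5G24780, 0.41 ± 0.16 and 1.11 ± 0.15) rose. The cold regulators CBF1 (AT4G25490, -2.08 ± 0.17 and -2.01 ± 0.21) and CBF2 (AT4G25470, -2.40 ± 0.45 and -1.99 ± 0.36) and the drought-responsive RD22 (AT5G25610, -1.92 ± 0.27 and -1.35 ± 0.23) fell. Anthocyanin genes DFR (AT5G42800, -1.16 ± 0.13 and -1.05 ± 0.14), UF3GT (AT5G54060, -0.95 ± 0.14 and -1.05 ± 0.21) and TT19 (AT5G17220, -1.03 ± 0.16 and -0.70 ± 0.20) fell, as did CYP83A1 (AT4G13770, -1.24 ± 0.18 and -0.55 ± 0.13) and BCAT4 (AT3G19710, -1.37 ± 0.18 and -0.70 ± 0.16) of aliphatic glucosinolate synthesis. Of 22 seed maturation genes, 11 rose and 6 fell as deposited, and 1 and 5 of 13 after subtraction (11 and 7, then 2 and 6, adjusted over the list alone, camera adjusted p = 0.97 and 0.00124, adjusted p = 0.995 and 0.771 with an estimated correlation). Of 20 jasmonate genes, 4 rose and 9 fell as deposited, and 3 and 5 of 18 after subtraction (4 and 9, then 4 and 6, adjusted over the list alone, camera adjusted p = 0.0741 and 0.187). Of 22 ABA, cold and drought genes, 1 rose and 10 fell as deposited, and 2 and 3 of 22 after subtraction (1 and 10, then 2 and 3, adjusted over the list alone, camera adjusted p = 0.0148 and 0.524, adjusted p = 0.868 and 0.916 with an estimated correlation). Of 19 flavonoid and anthocyanin genes, 4 rose and 6 fell as deposited, and 0 and 4 of 15 after subtraction (4 and 5, then 2 and 5, adjusted over the list alone, camera adjusted p = 0.465 and 0.758, deposited median -0.27, mean 0.10 and test pointing down, subtracted median 0.11, mean -0.11 and test pointing down). Of 19 glucosinolate genes, 2 rose and 15 fell as deposited, and 1 and 2 of 16 after subtraction (2 and 15, then 1 and 4, adjusted over the list alone, camera adjusted p = 0.00239 and 0.081, adjusted p = 0.868 and 0.776 with an estimated correlation). Reads of AOC1 and AOC2, and of CBF1 and CBF2, may be split between near-identical copies. VSP1 (0.42, 0.39 and 0.22) lost the deposited call without Col-0 replicate 1 or 2 or lhp1-3 replicate 1. CBF2 (-2.35 and -2.41) lost the deposited call without lhp1-3 replicate 1 or 2. CBF2 (-1.72) shifted as deposited without Col-0 replicate 2. ABI5 (0.69, 0.72, 0.56 and 0.84) and CYP83A1 (-0.56, -0.54, -0.53 and -0.56) lost the subtracted calls without each Col-0 or lhp1-3 library in turn. CBF2 (-1.97), UF3GT (-0.97) and RD22 (-1.17) lost the subtracted calls without lhp1-3 replicate 1. CBF2 (-2.01) and UF3GT (-1.12) lost the subtracted calls without lhp1-3 replicate 2. TT19 (-0.39, -0.76, -0.64, -0.68 and -0.68) lost the subtracted call without Col-0 replicate 1, lhp1-3 replicate 1 or 2 or importin123 replicate 1 or 2. BCAT4 (-0.48, -0.82, -0.59, -0.68 and -0.68) lost the subtracted call without Col-0 replicate 2, lhp1-3 replicate 1 or 2 or importin123 replicate 1 or 2. CBF2 (-1.31) shifted after subtraction without Col-0 replicate 2.

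Several genes of the Polycomb system itself rose in lhp1-3. They included the histone methyltransferase gene CLF (AT2G23380, 0.58 ± 0.12 and 0.75 ± 0.14), the Polycomb partner EMF1 (AT5G11530, 1.24 ± 0.14 and 1.71 ± 0.19) and the demethylase gene REF6 (AT3G48430, 0.49 ± 0.13 and 0.93 ± 0.13). The methyltransferase gene SWN (AT4G02020, 0.24 ± 0.12 and 0.67 ± 0.11) passed after subtraction alone, as did the triterpene enzyme genes THAH (AT5G48000, 0.06 ± 0.16 and 0.74 ± 0.14) and CYP71A16 (AT5G42590, 0.24 ± 0.14 and 0.75 ± 0.18). The heat-shock regulator HSFA2 (AT2G26150, 0.98 ± 0.19 and 1.0 ± 0.24) rose. Among light-harvesting genes LHCB1.1 (AT1G29920, 0.81 ± 0.24 and 1.52 ± 0.23) rose, although its reads may be shared with LHCB1.2, and LHCB3 (AT5G54270, -1.48 ± 0.18 and -0.81 ± 0.16) and LHCA1 (AT3G54890, -1.49 ± 0.22 and -0.78 ± 0.17) fell. The auxin efflux genes PIN4 (AT2G01420, -1.32 ± 0.16 and -0.72 ± 0.13) and PIN7 (AT1G23080, -1.30 ± 0.15 and -0.71 ± 0.12), the stress zinc-finger genes ZAT12 (AT5G59820, -1.30 ± 0.17 and -0.59 ± 0.16) and ZAT10 (AT1G27730, -1.34 ± 0.20 and -0.63 ± 0.17) and the immune regulator CBP60G (AT5G26920, -1.74 ± 0.20 and -1.23 ± 0.20) fell. In the clock, PRR3 (AT5G60100, 1.01 ± 0.18 and 1.33 ± 0.29) rose and LUX (AT3G46640, -0.90 ± 0.13 and -0.37 ± 0.09) and ZTL (AT5G57360, -0.98 ± 0.14 and -0.37 ± 0.09) fell. Of 24 Polycomb and related chromatin genes, 12 rose and 4 fell as deposited, and 6 and 1 of 17 after subtraction (12 and 4, then 8 and 1, adjusted over the list alone, camera adjusted p = 0.416 and 0.0176, adjusted p = 0.868 and 0.729 with an estimated correlation). Of 6 triterpene cluster genes, 0 rose and 1 fell as deposited, and 2 and 0 of 6 after subtraction (0 and 0, then 4 and 0, adjusted over the list alone, camera adjusted p = 0.719 and 0.0188, adjusted p = 0.922 and 0.776 with an estimated correlation, deposited median 0.02, mean -0.03 and test pointing down). Of 13 heat-shock genes, 7 rose and 2 fell as deposited, and 2 and 0 of 9 after subtraction (7 and 2, then 5 and 0, adjusted over the list alone, camera adjusted p = 0.301 and 0.0274, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 21 leaf photosynthesis genes, 1 rose and 17 fell as deposited, and 1 and 6 of 21 after subtraction (1 and 17, then 1 and 8, adjusted over the list alone, camera adjusted p = 5.09e-05 and 0.0384, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 23 auxin genes, 8 rose and 9 fell as deposited, and 1 and 3 of 17 after subtraction (8 and 9, then 1 and 3, adjusted over the list alone, camera adjusted p = 0.797 and 0.331, deposited median -0.08, mean 0.28 and test pointing down). Of 11 touch and wound genes, 0 rose and 11 fell as deposited, and 0 and 3 of 11 after subtraction (0 and 11, then 0 and 4, adjusted over the list alone, camera adjusted p = 0.00126 and 0.0354, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 19 salicylic acid defence genes, 3 rose and 6 fell as deposited, and 1 and 2 of 12 after subtraction (3 and 6, then 1 and 3, adjusted over the list alone, camera adjusted p = 0.362 and 0.298). Of 23 circadian clock genes, 8 rose and 12 fell as deposited, and 1 and 5 of 20 after subtraction (8 and 12, then 3 and 5, adjusted over the list alone, camera adjusted p = 0.242 and 0.609, subtracted median -0.10, mean 0.02 and test pointing down). REF6 (0.43) lost the deposited call without lhp1-3 replicate 1. LHCB1.1 (0.50) lost the deposited call without lhp1-3 replicate 2. CLF (0.62), LHCB3 (-0.63) and LHCA1 (-0.77) lost the subtracted calls without Col-0 replicate 2. CLF (0.73), LHCB3 (-0.64), LHCA1 (-0.61), SWN (0.60), PIN4 (-0.54) and PIN7 (-0.56) lost the subtracted calls without lhp1-3 replicate 1. THAH (0.59, 0.74 and 0.75) and CYP71A16 (0.55, 0.86 and 0.65) lost the subtracted calls without Col-0 replicate 2 or lhp1-3 replicate 1 or 2. HSFA2 (0.95, 1.05, 0.97 and 1.05), LUX (-0.33, -0.41, -0.33 and -0.40) and ZTL (-0.35, -0.40, -0.37 and -0.37) lost the subtracted calls without each Col-0 or lhp1-3 library in turn. ZAT12 (-0.33, -0.58, -0.60, -0.57 and -0.57) and ZAT10 (-0.36, -0.60, -0.65, -0.60 and -0.60) lost the subtracted calls without Col-0 replicate 2, lhp1-3 replicate 1 or 2 or importin123 replicate 1 or 2. CBP60G (-1.23 and -1.22) lost the subtracted call without lhp1-3 replicate 1 or 2. PRR3 (1.16, 0.85, 1.36 and 1.36) lost the subtracted call without Col-0 replicate 2, lhp1-3 replicate 1 or importin123 replicate 1 or 2.

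In lhp1-3, of 11 reference genes, 0 rose and 11 fell as deposited, and 0 and 0 of 11 after subtraction (0 and 11, then 0 and 0, adjusted over the list alone, camera adjusted p = 5.67e-04 and 0.331, adjusted p = 0.868 and 0.789 with an estimated correlation, subtracted counts of 0 and 1 at an unadjusted p under 0.05 and 0 and 1 in DESeq2). Of 11 anther and pollen genes, 10 rose and 1 fell as deposited, and 0 and 1 of 2 after subtraction, too few for camera. The counts adjusted over the list alone were the same (camera adjusted p = 0.0121, and 0.868 with an estimated correlation). The rest lay near the floor, which may give their rises. Of 22 root marker genes, 7 rose and 3 fell as deposited, and 1 and 1 of 18 after subtraction (6 and 3, then 0 and 0, adjusted over the list alone, camera adjusted p = 0.925 and 0.0397, adjusted p = 0.994 and 0.776 with an estimated correlation). Among the largest single rises, LURE1.4 (AT5G43518, 3.81 ± 0.47), GRP16 (AT5G07540, 3.70 ± 0.37) and AGL97 (AT1G46408, 3.54 ± 0.45) came from the floor, and the sugar transporter gene SWEET10 (AT5G50790, 3.45 ± 0.35 and 5.09 ± 1.09) passed on both sets of counts. After subtraction MIR5642b (AT2G03855, 3.04 ± 0.19 and 3.77 ± 0.22) and LURE1.2 (AT5G43510, 2.65 ± 0.43 and 3.71 ± 0.73) joined the largest rises, with hda17 (AT3G44490, 3.18 ± 0.30). The largest falls beyond the seed genes were LBD32 (AT4G22700, -3.46 ± 0.17 and -2.98 ± 0.19) and BGLU19 (AT3G21370, -2.78 ± 0.25 and -2.5 ± 0.20) and, to the floor, RPL12-B (AT3G27840, -4.01 ± 0.18), MRD1 (AT1G53480, -3.61 ± 0.14), MIR853 (AT3G23326, -2.75 ± 0.35), HEI10 (AT1G53490, -2.55 ± 0.12) and DCF (AT3G48720, -1.92 ± 0.14). U2.3 (AT3G09005, -2.90 ± 0.37 and -3.53 ± 0.96) fell as deposited, with adjusted p = 0.0537 after subtraction. LURP1 (AT2G14560, -1.10 ± 0.51) was not called as deposited and fell to the floor after subtraction. LURE1.4 (4.57), SWEET10 (4.22) and LURE1.2 (3.28) shifted as deposited without Col-0 replicate 2. AGL97 (2.89 and 4.95) shifted as deposited without Col-0 replicate 1 or 2. U2.3 (-3.55) shifted as deposited without lhp1-3 replicate 2. SWEET10 (5.11 and 5.10) lost the subtracted call without lhp1-3 replicate 1 or 2. LURE1.2 (2.99) lost the subtracted call without lhp1-3 replicate 2. SWEET10 (4.22) and LURE1.2 (3.03) shifted after subtraction without Col-0 replicate 1. SWEET10 (8.35) and LURE1.2 (5.29) shifted after subtraction without Col-0 replicate 2. LURP1 lost the subtracted call without lhp1-3 replicate 1 (adjusted p = 0.0904). MIR853 lost the subtracted call without lhp1-3 replicate 1 or 2 (adjusted p = 0.117 to 0.191).

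In all, 14172 genes were higher and 11368 lower in lhp1-3 than in Col-0 among 33906 tested as deposited (edgeR quasi-likelihood test, Benjamini-Hochberg), and 11714 and 1898 of these changed at least 2-fold. Of the higher genes, 84.5% lay within 2 times the floor in lhp1-3. After subtraction 1784 genes were higher and 1408 lower among 19689, of which 775 and 395 changed at least 2-fold. Of the 14172 higher genes, 2049 could be tested after subtraction and 1134 of them stayed higher. Of the 11368 lower genes, 11184 could be tested and 1388 stayed lower, while 4 became higher. The subtracted counts moved strongly with the size of the floor, from 3607 higher and 2541 lower with a floor smaller by 25% to 1295 and 854 with one larger by 25%. Without lhp1-3 replicate 1 the lower genes numbered 7489 as deposited, and the subtracted counts were 481 higher and 266 lower. The subtracted counts were 959 and 530 without Col-0 replicate 2, and the lower genes numbered 708 without lhp1-3 replicate 2.

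The second comparison was importin123 against Col-0. Named cold, seed and anthocyanin genes rose in importin123, and named glucosinolate genes fell. The cold-regulated COR15A (AT2G42540, 5.92 ± 0.59 and 6.81 ± 0.43), RD29A (AT5G52310, 3.17 ± 0.65 and 3.94 ± 0.50), KIN1 (AT5G15960, 2.92 ± 0.43 and 3.68 ± 0.31) and KIN2 (AT5G15970, 1.95 ± 0.19 and 2.72 ± 0.15) rose, with the ABA-responsive RAB18 (AT5G66400, 2.31 ± 0.32 and 3.06 ± 0.26), HAI2 (AT1G07430, 2.60 ± 0.17 and 3.44 ± 0.19) and RD22 (0.78 ± 0.26 and 1.52 ± 0.23). COR15A went from 5.05 ± 0.404 to 307 ± 184 CPM (SD, n = 2). The upstream regulators CBF1 (-1.77 ± 0.17 and -1.47 ± 0.21) and DREB2A (AT5G05410, -1.74 ± 0.15 and -1.20 ± 0.15) fell. Seed genes SESA3 (AT4G27160, 2.99 ± 0.34 and 4.31 ± 0.59), EM1 (AT3G51810, 1.5 ± 0.28 and 2.24 ± 0.42), CRA1 (0.75 ± 0.22 and 1.5 ± 0.19), OLEO1 (0.68 ± 0.12 and 1.43 ± 0.11) and ABI5 (0.92 ± 0.15 and 1.26 ± 0.20) rose, and CRU3 (0.57 ± 0.43 and 1.31 ± 0.33) passed after subtraction alone. Anthocyanin enzyme and transport genes DFR (2.35 ± 0.13 and 3.15 ± 0.14), UF3GT (2.16 ± 0.14 and 2.95 ± 0.21), LDOX (AT4G22880, 2.07 ± 0.15 and 2.86 ± 0.21) and TT19 (1.96 ± 0.16 and 2.74 ± 0.20) rose with their regulator PAP1 (AT1G56650, 1.52 ± 0.19 and 2.04 ± 0.23). The aliphatic glucosinolate genes CYP79F1 (AT1G16410, -3.73 ± 0.29 and -3.48 ± 0.42), MAM1 (AT5G23010, -3.61 ± 0.25 and -3.15 ± 0.28), BCAT4 (-2.74 ± 0.19 and -2.14 ± 0.17), CYP83A1 (-2.54 ± 0.19 and -1.86 ± 0.14) and MYB29 (AT5G07690, -1.67 ± 0.16 and -2.26 ± 0.32) fell, and MAM3 (AT5G23020, 0.29 ± 0.16 and 0.94 ± 0.24) passed after subtraction alone, upward. Of 22 ABA, cold and drought genes, 12 rose and 3 fell as deposited, and 16 and 2 of 22 after subtraction (12 and 3, then 19 and 3, adjusted over the list alone, camera adjusted p = 0.335 and 1.39e-05, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 22 seed maturation genes, 15 rose and 0 fell as deposited, and 9 and 0 of 13 after subtraction (15 and 0, then 9 and 0, adjusted over the list alone, camera adjusted p = 0.00366 and 1.47e-04, adjusted p = 0.868 and 0.729 with an estimated correlation). Of 19 flavonoid and anthocyanin genes, 10 rose and 5 fell as deposited, and 7 and 1 of 15 after subtraction (10 and 5, then 7 and 1, adjusted over the list alone, camera adjusted p = 0.391 and 0.0222, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 19 glucosinolate genes, 2 rose and 15 fell as deposited, and 1 and 11 of 16 after subtraction (2 and 15, then 1 and 11, adjusted over the list alone, camera adjusted p = 3.42e-04 and 2.94e-04, adjusted p = 0.868 and 0.729 with an estimated correlation). KIN1 and KIN2 are near-identical copies whose reads may be shared. RD29A (3.32, 3.03 and 3.27) lost the deposited call without Col-0 replicate 1 or 2 or lhp1-3 replicate 1. RD22 (0.33) and CRA1 (0.36) lost the deposited calls without importin123 replicate 2. COR15A (6.54) and RD29A (3.86) shifted as deposited without importin123 replicate 1. COR15A (5.16) and RD29A (2.25) shifted as deposited without importin123 replicate 2. SESA3 (3.67) shifted as deposited without Col-0 replicate 2. RD29A (3.78) lost the subtracted call without Col-0 replicate 2. CRU3 (0.83) lost the subtracted call without importin123 replicate 2. MAM3 (0.74 and 0.70) lost the subtracted call without Col-0 replicate 1 or importin123 replicate 1. COR15A (6.18), RD29A (3.11) and CYP79F1 (-4.25) shifted after subtraction without importin123 replicate 2. SESA3 (3.63 and 5.87) shifted after subtraction without Col-0 replicate 1 or 2. EM1 (1.59) shifted after subtraction without importin123 replicate 1.

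Jasmonate, clock and photosynthesis genes split in importin123. The jasmonate synthesis genes AOC2 (1.43 ± 0.20 and 2.19 ± 0.18) and LOX2 (AT3G45140, 1.05 ± 0.23 and 1.80 ± 0.22) rose, AOS (-0.04 ± 0.18 and 0.72 ± 0.15) passed after subtraction alone (adjusted p = 0.843 as deposited and 0.00756 after), and VSP1 (-1.36 ± 0.16 and -0.66 ± 0.15) fell. The clock genes PRR7 (AT5G02810, 2.25 ± 0.15 and 3.03 ± 0.33), LNK1 (AT5G64170, 2.2 ± 0.13 and 2.96 ± 0.16) and GI (AT1G22770, 0.97 ± 0.14 and 1.65 ± 0.12) rose and the morning genes RVE4 (AT5G02840, -1.41 ± 0.14 and -0.87 ± 0.11) and RVE1 (AT5G17300, -1.08 ± 0.12 and -0.84 ± 0.13) fell. The light-harvesting genes LHCB1.1 (2.45 ± 0.25 and 3.22 ± 0.25), LHCB1.2 (AT1G29910, 2.26 ± 0.22 and 3.04 ± 0.21) and LHCA4 (AT3G47470, 0.53 ± 0.21 and 1.29 ± 0.17) rose, the first pair being near-identical copies, while LHCB4.1 (AT5G01530, -1.52 ± 0.23 and -0.75 ± 0.17) and RBCS3B (AT5G38410, -1.89 ± 0.27 and -1.11 ± 0.17) fell. The auxin synthesis gene YUC8 (AT4G28720, 1.07 ± 0.17 and 1.59 ± 0.21) rose and GH3.5 (AT4G27260, -1.38 ± 0.16 and -0.86 ± 0.16), which conjugates auxin, fell. The root hair regulator RHD6 (AT1G66470, 2.03 ± 0.20 and 2.73 ± 0.29) rose, whereas SCR (AT3G54220, -1.15 ± 0.12 and -0.61 ± 0.10), needed for the root endodermis, and the phosphate transporter gene PHT1;1 (AT5G43350, -1.72 ± 0.15 and -1.05 ± 0.14) fell. Touch and stress genes ZAT12 (-2.25 ± 0.18 and -1.50 ± 0.16), TCH2 (AT5G37770, -1.69 ± 0.18 and -0.96 ± 0.16) and ZAT10 (-1.75 ± 0.20 and -0.98 ± 0.17) fell, as did the chaperone genes HSP70 (AT3G12580, -1.43 ± 0.17 and -0.75 ± 0.14) and HSP90.1 (AT5G52640, -1.23 ± 0.13 and -0.79 ± 0.13). In defence, WRKY54 (AT2G40750, 0.97 ± 0.20 and 1.39 ± 0.28) rose and CBP60G (-2.00 ± 0.20 and -1.49 ± 0.21) fell. Of 20 jasmonate genes, 5 rose and 5 fell as deposited, and 7 and 2 of 18 after subtraction (4 and 5, then 7 and 2, adjusted over the list alone, camera adjusted p = 0.659 and 0.0745, deposited median -0.02, mean 0.06 and test pointing down). Of 23 circadian clock genes, 9 rose and 11 fell as deposited, and 7 and 5 of 20 after subtraction (9 and 11, then 7 and 5, adjusted over the list alone, camera adjusted p = 0.596 and 0.195, deposited median -0.28, mean 0.17 and test pointing down). Of 21 leaf photosynthesis genes, 6 rose and 13 fell as deposited, and 8 and 7 of 21 after subtraction (6 and 13, then 8 and 8, adjusted over the list alone, camera adjusted p = 0.03 and 0.81, adjusted p = 0.868 and 0.945 with an estimated correlation, subtracted median -0.03, mean 0.36 and test pointing up). Of 23 auxin genes, 9 rose and 8 fell as deposited, and 3 and 2 of 17 after subtraction (9 and 9, then 3 and 1, adjusted over the list alone, camera adjusted p = 0.999 and 0.81). Of 22 root marker genes, 7 rose and 3 fell as deposited, and 4 and 2 of 18 after subtraction (7 and 3, then 4 and 2, adjusted over the list alone, camera adjusted p = 0.596 and 0.0615). Of 11 touch and wound genes, 0 rose and 11 fell as deposited, and 0 and 7 of 11 after subtraction (0 and 11, then 0 and 7, adjusted over the list alone, camera adjusted p = 3.80e-04 and 0.00512, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 13 heat-shock genes, 7 rose and 4 fell as deposited, and 1 and 4 of 9 after subtraction (7 and 4, then 1 and 4, adjusted over the list alone, camera adjusted p = 0.657 and 0.732, subtracted median 0.26, mean -0.01 and test pointing down). Of 19 salicylic acid defence genes, 5 rose and 4 fell as deposited, and 1 and 1 of 12 after subtraction (5 and 4, then 1 and 1, adjusted over the list alone, camera adjusted p = 0.657 and 0.732, deposited median -0.20, mean 0.19 and test pointing down). LHCA4 (0.39, 0.52 and 0.23) lost the deposited call without Col-0 replicate 1, lhp1-3 replicate 2 or importin123 replicate 2. VSP1 (-0.66 and -0.64) lost the subtracted call without importin123 replicate 1 or 2.

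Floral genes went both ways in importin123. SEP4 (-0.54 ± 0.13 and -0.93 ± 0.20) fell. PI (2.15 ± 0.18 and 2.88 ± 0.25) rose but passed the filter only with lhp1-3 libraries. AP3 (2.36 ± 0.24) and SEP1 (1.16 ± 0.15) rose as deposited but lay near the floor, as did SEP3 (0.77 ± 0.33), not called. FT (-0.40 ± 0.16 and -0.66 ± 0.36) fell as deposited alone (adjusted p = 0.192 after subtraction). SPL4 (1.46 ± 0.29 and 1.74 ± 0.52) rose and SPL3 (-0.58 ± 0.20 and -0.96 ± 0.23) fell. The floral repressors SVP (-1.47 ± 0.15 and -0.96 ± 0.12) and TEM2 (-1.42 ± 0.19 and -0.65 ± 0.16) fell. The leaf and boundary regulators AS1 (AT2G37630, -1.22 ± 0.14 and -0.54 ± 0.11), BOP2 (AT2G41370, -0.96 ± 0.13 and -0.59 ± 0.13) and RPL (-0.83 ± 0.13 and -0.58 ± 0.13) fell. Polycomb genes CLF (0.81 ± 0.12 and 1.19 ± 0.14) and EMF1 (0.67 ± 0.14 and 0.92 ± 0.19) rose, and SWN (0.11 ± 0.12 and 0.55 ± 0.11) and REF6 (0.24 ± 0.13 and 0.64 ± 0.13) passed after subtraction alone. The triterpene enzyme gene CYP71A16 (0.54 ± 0.14 and 1.18 ± 0.18) rose. Of 15 floral MADS-box genes, 12 rose and 1 fell as deposited, and 2 and 3 of 6 after subtraction (12 and 1, then 2 and 3, adjusted over the list alone, camera adjusted p = 0.00267 and 0.521, adjusted p = 0.868 and 0.776 with an estimated correlation). Of these subtracted calls, AP3 up and SEP1 and SEP3 down lay near the floor. Of 27 flowering-time genes, 12 rose and 6 fell as deposited, and 3 and 5 of 16 after subtraction (12 and 6, then 3 and 5, adjusted over the list alone, camera adjusted p = 0.657 and 0.732). Of 19 meristem and boundary genes, 9 rose and 3 fell as deposited, and 0 and 4 of 7 after subtraction (9 and 3, then 0 and 5, adjusted over the list alone, camera adjusted p = 0.421 and 0.14). Of 24 Polycomb and related chromatin genes, 10 rose and 5 fell as deposited, and 7 and 1 of 17 after subtraction (10 and 5, then 7 and 1, adjusted over the list alone, camera adjusted p = 0.657 and 0.14). Of 6 triterpene cluster genes, 1 rose and 3 fell as deposited, and 2 and 0 of 6 after subtraction (1 and 3, then 2 and 0, adjusted over the list alone, camera adjusted p = 0.354 and 0.166). SEP4 (-0.38) lost the deposited call without importin123 replicate 1. FT (-0.32, -0.32 and -0.11) lost the deposited call without Col-0 replicate 1, lhp1-3 replicate 1 or importin123 replicate 1. SPL3 (-0.49, -0.51, -0.54 and -0.48) lost the deposited call without Col-0 replicate 2, lhp1-3 replicate 1 or importin123 replicate 1 or 2. CYP71A16 (0.35) lost the deposited call without Col-0 replicate 2. SPL4 (1.46, 1.76, 1.74 and 0.87) lost the subtracted call without Col-0 replicate 1, lhp1-3 replicate 1 or 2 or importin123 replicate 1. SPL3 (-0.87) lost the subtracted call without Col-0 replicate 2. TEM2 (-0.53 and -0.55) lost the subtracted call without Col-0 replicate 2 or importin123 replicate 2. BOP2 (-0.49) and RPL (-0.44) lost the subtracted calls without importin123 replicate 1. EMF1 (0.77) lost the subtracted call without importin123 replicate 2. AP3 lost the subtracted call without Col-0 replicate 2, lhp1-3 replicate 1 or 2 or importin123 replicate 1 (adjusted p = 0.0683 to 0.189). SEP3 lost the subtracted call without importin123 replicate 1 or 2 (adjusted p = 0.0615 to 0.103).

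The largest single rises in importin123 beside COR15A were BHLH100 (AT2G41240, 5.87 ± 0.21 and 7.62 ± 0.72), bHLH38 (AT3G56970, 5.01 ± 0.17 and 6.24 ± 0.27) and bHLH39 (AT3G56980, 4.50 ± 0.20 and 5.62 ± 0.35), transcription factor genes of the iron deficiency response, the lipid transfer protein gene LTP4 (AT5G59310, 5.83 ± 0.64 and 7.61 ± 0.68), the Nudix hydrolase gene NUDT24 (AT5G19470, 4.77 ± 0.36 and 6.77 ± 1.3) and the heat-shock factor gene HSFA6A (AT5G43840, 3.66 ± 0.27 and 5.43 ± 0.40). GRP16 (3.61 ± 0.37) and hda17 (3.06 ± 0.30) came from the floor. The largest falls beside IMPA2, MRD1 and CYP79F1 were those of CYP81D11 (AT3G28740, -4.95 ± 0.19 and -4.62 ± 0.18), NEET (AT5G51720, -4.87 ± 0.16 and -4.80 ± 0.13), GRP3S (AT2G05380, -4.48 ± 0.21 and -3.83 ± 0.16), SEN1 (AT4G35770, -4.31 ± 0.17 and -4.21 ± 0.18) and RPL12-B (-3.70 ± 0.18 and -4.04 ± 0.27), where CYP81D11 encodes a cytochrome P450, NEET an iron-sulfur protein and SEN1 a product of darkened leaves. MRD1 (-3.78 ± 0.15), HEI10 (-2.56 ± 0.12) and MIR5640 (AT1G04393, -1.84 ± 0.37) fell to the floor. Of 11 reference genes, 0 rose and 9 fell as deposited, and 1 and 0 of 11 after subtraction (0 and 9, then 0 and 0, adjusted over the list alone, camera adjusted p = 0.00172 and 0.897, adjusted p = 0.868 and 0.945 with an estimated correlation, subtracted median -0.08, mean 0.01 and test pointing down). Of 11 anther and pollen genes, 10 rose and 1 fell as deposited, and 0 and 1 of 2 after subtraction, too few for camera. The counts adjusted over the list alone were the same (camera adjusted p = 0.0148, and 0.868 with an estimated correlation). The floor may give these rises too. LTP4 (5.19) shifted as deposited without importin123 replicate 2. NUDT24 (5.43) shifted as deposited without Col-0 replicate 2. NUDT24 (6.0, 9.0 and 6.63) lost the subtracted call without Col-0 replicate 1 or 2 or importin123 replicate 1. bHLH39 (6.30) shifted after subtraction without Col-0 replicate 1. LTP4 (9.18 and 6.80) shifted after subtraction without Col-0 replicate 1 or 2. MIR5640 lost the subtracted call without importin123 replicate 1 or 2 (adjusted p = 0.0734 to 0.116).

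In all, 14351 genes were higher and 11251 lower in importin123 than in Col-0 among 33906 tested as deposited (edgeR quasi-likelihood test, Benjamini-Hochberg), and 11849 and 3676 of these changed at least 2-fold. Of the higher genes, 81.3% lay within 2 times the floor in importin123. After subtraction 3797 genes were higher and 4277 lower among 19689, of which 1367 and 1157 changed at least 2-fold. Of the 14351 higher genes, 2342 could be tested after subtraction, 1855 stayed higher and 3 became lower. Of the 11251 lower genes, 11058 could be tested, 4214 stayed lower and 154 became higher. The subtracted counts were 5288 higher and 4931 lower with the smaller floor, and 3467 and 3621 with the larger one. Without importin123 replicate 1 they were 2294 higher and 2696 lower, and without Col-0 replicate 2 the higher genes numbered 2406.

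Comparing importin123 with lhp1-3 tested the difference between the mutants. Named seed, cold, jasmonate and anthocyanin genes were higher in importin123, and named floral and glucosinolate genes were lower. Higher genes included the seed genes CRU3 (4.91 ± 0.51 and 5.56 ± 0.40), CRA1 (4.37 ± 0.25 and 4.59 ± 0.21) and OLEO1 (3.00 ± 0.13 and 3.46 ± 0.12), the cold and ABA genes COR15A (5.97 ± 0.59 and 7.05 ± 0.43), KIN1 (3.27 ± 0.44 and 3.47 ± 0.31), RAB18 (3.45 ± 0.33 and 3.52 ± 0.27) and RD22 (2.70 ± 0.28 and 2.87 ± 0.24), the jasmonate genes AOC2 (3.81 ± 0.22 and 3.96 ± 0.19), AOS (2.14 ± 0.19 and 2.26 ± 0.16) and LOX2 (1.95 ± 0.24 and 2.03 ± 0.22) and the anthocyanin genes DFR (3.5 ± 0.14 and 4.20 ± 0.15), UF3GT (3.11 ± 0.15 and 4.0 ± 0.22) and LDOX (3.05 ± 0.15 and 3.57 ± 0.22). The iron-related BHLH100 (4.53 ± 0.18) and bHLH38 (4.04 ± 0.15) were higher, with lhp1-3 at the floor. Clock genes LNK1 (1.3 ± 0.13 and 2.43 ± 0.15) and GI (1.48 ± 0.14 and 1.91 ± 0.12) and PRR7 (1.69 ± 0.14) were higher, as were LHCB1.2 (2.58 ± 0.22 and 2.65 ± 0.20) and LHCA4 (1.89 ± 0.22 and 1.94 ± 0.17). The floral genes SEP4 (-1.42 ± 0.13 and -2.30 ± 0.20), PI (-0.88 ± 0.16 and -1.41 ± 0.22) and FT (-2.03 ± 0.16 and -2.93 ± 0.37) and, with importin123 near the floor, SEP3 (-3.65 ± 0.31), SEP1 (-3.17 ± 0.14) and AP3 (-1.64 ± 0.20) were lower. Lower genes also included RPL (-1.27 ± 0.13 and -1.59 ± 0.14), VSP1 (-1.77 ± 0.16 and -1.78 ± 0.15) and HSP90.1 (-1.09 ± 0.13 and -1.24 ± 0.13), the glucosinolate genes CYP79F1 (-2.54 ± 0.27 and -2.95 ± 0.41), MAM1 (-2.23 ± 0.24 and -2.44 ± 0.27) and BCAT4 (-1.37 ± 0.18 and -1.44 ± 0.17), and CYP81D11 (-3.83 ± 0.18 and -4.20 ± 0.18), UGT74E2 (AT1G05680, -3.74 ± 0.15 and -4.34 ± 0.17) and NEET (-3.63 ± 0.15 and -4.24 ± 0.13) with IMPA2 (-3.52 ± 0.16). LHP1 (0.67 ± 0.13 and 1.07 ± 0.15) was higher. After subtraction the largest differences also took in LURP1 (3.94 ± 0.54) and NUDT24 (3.11 ± 0.32) upward and MIR5026 (AT4G06075, -3.13 ± 0.37) and SWEET10 (-1.93 ± 0.31) downward. SAG29 (AT5G13170, 3.08 ± 0.51) was not called as deposited (adjusted p = 0.0615) and was called after subtraction, with lhp1-3 at the floor. CRU3 (5.0), COR15A (6.03), KIN1 (3.23) and LURP1 (3.96) lost the deposited calls without lhp1-3 replicate 1. CRU3 (4.87), COR15A (5.96), KIN1 (3.36), LURP1 (3.97) and LHP1 (0.57) lost the deposited calls without lhp1-3 replicate 2. SWEET10 (-1.68) lost the deposited call without importin123 replicate 2. CRU3 (4.27), COR15A (5.16), KIN1 (2.68) and RAB18 (2.83) shifted as deposited without importin123 replicate 2. COR15A (6.39), FT (-3.65) and CYP79F1 (-3.74) shifted after subtraction without importin123 replicate 2. NUDT24 lost the subtracted call without each Col-0 or importin123 library in turn (adjusted p = 0.0732 to 0.129). SWEET10 lost the subtracted call without each lhp1-3 or importin123 library in turn (adjusted p = 0.056 to 0.0622).

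Several lists were called between the mutants. Of 15 floral MADS-box genes, 0 were higher and 8 lower as deposited, and 0 and 6 of 6 after subtraction (0 and 9, then 0 and 6, adjusted over the list alone, camera adjusted p = 8.71e-08 as deposited, adjusted p = 0.868 with an estimated correlation). All but SEP4 entered the subtracted count through their level in lhp1-3. Of 22 seed maturation genes, 8 were higher and 0 lower as deposited, and 12 and 0 of 13 after subtraction (11 and 0, then 13 and 0, adjusted over the list alone, camera adjusted p = 3.01e-11 and 2.50e-09, adjusted p = 0.868 and 0.55 with an estimated correlation). Of 22 ABA, cold and drought genes, 12 were higher and 1 lower as deposited, and 14 and 1 of 22 after subtraction (15 and 1, then 19 and 1, adjusted over the list alone, camera adjusted p = 2.20e-14 and 2.50e-09, adjusted p = 0.868 and 0.729 with an estimated correlation). Of 19 glucosinolate genes, 1 were higher and 10 lower as deposited, and 1 and 12 of 16 after subtraction (1 and 12, then 1 and 12, adjusted over the list alone, camera adjusted p = 5.25e-07 and 1.08e-04, adjusted p = 0.868 and 0.729 with an estimated correlation). Of 20 jasmonate genes, 4 were higher and 1 lower as deposited, and 6 and 1 of 18 after subtraction (5 and 1, then 6 and 1, adjusted over the list alone, camera adjusted p = 5.02e-04 and 0.00499, adjusted p = 0.868 and 0.776 with an estimated correlation). Of 19 meristem and boundary genes, 0 were higher and 4 lower as deposited, and 0 and 5 of 7 after subtraction (0 and 6, then 0 and 6, adjusted over the list alone, camera adjusted p = 0.0235 and 7.11e-04, adjusted p = 0.868 and 0.54 with an estimated correlation). Called as deposited alone were 19 flavonoid and anthocyanin genes (7 higher, 2 lower, camera adjusted p = 0.0164, and 0.108 after subtraction), 23 circadian clock genes (5 higher, 3 lower, camera adjusted p = 0.0164, and 0.0532 after subtraction), 21 leaf photosynthesis genes (9 higher, 2 lower, camera adjusted p = 0.0148, and 0.0745 after subtraction), 11 touch and wound genes (0 higher, 1 lower, camera adjusted p = 0.00893, and 0.0532 after subtraction) and 9 importin alpha genes (0 higher, 3 lower, camera adjusted p = 0.0207, and 0.081 after subtraction), each with adjusted p = 0.868 with an estimated correlation. Their counts adjusted over the list alone were 7 and 5, 5 and 3, 10 and 4, 0 and 1 and 0 and 3. The flavonoid list had a median of -0.11 and a mean of 0.68, with the test pointing up. Of 9 heat-shock genes testable after subtraction, 0 were higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.776 with an estimated correlation), and the list was not called as deposited (camera adjusted p = 0.106). The other 8 lists were not called on either set of counts where they could be tested. In all, 962 genes were higher and 2053 lower in importin123 than in lhp1-3 among 33906 tested as deposited (edgeR quasi-likelihood test, Benjamini-Hochberg), 316 and 391 of them by at least 2-fold. After subtraction the counts were 1801 and 2635 among 19689, with 622 and 644 at least 2-fold. Of the 962 higher genes 926 could be tested after subtraction and 922 stayed higher, and of the 2053 lower genes 2025 could be tested and 1992 stayed lower. The deposited count of higher genes was 1466 and 1468 without Col-0 replicate 1 or 2, 456 and 475 without lhp1-3 replicate 1 or 2, and 578 without importin123 replicate 2. That of lower genes was 756 and 876 without lhp1-3 replicate 1 or 2 and 605 without importin123 replicate 1. The subtracted counts were 777 and 1443 without lhp1-3 replicate 1, 1076 and 1429 without lhp1-3 replicate 2, and 755 and 1314 without importin123 replicate 1.

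**Figure D2:**
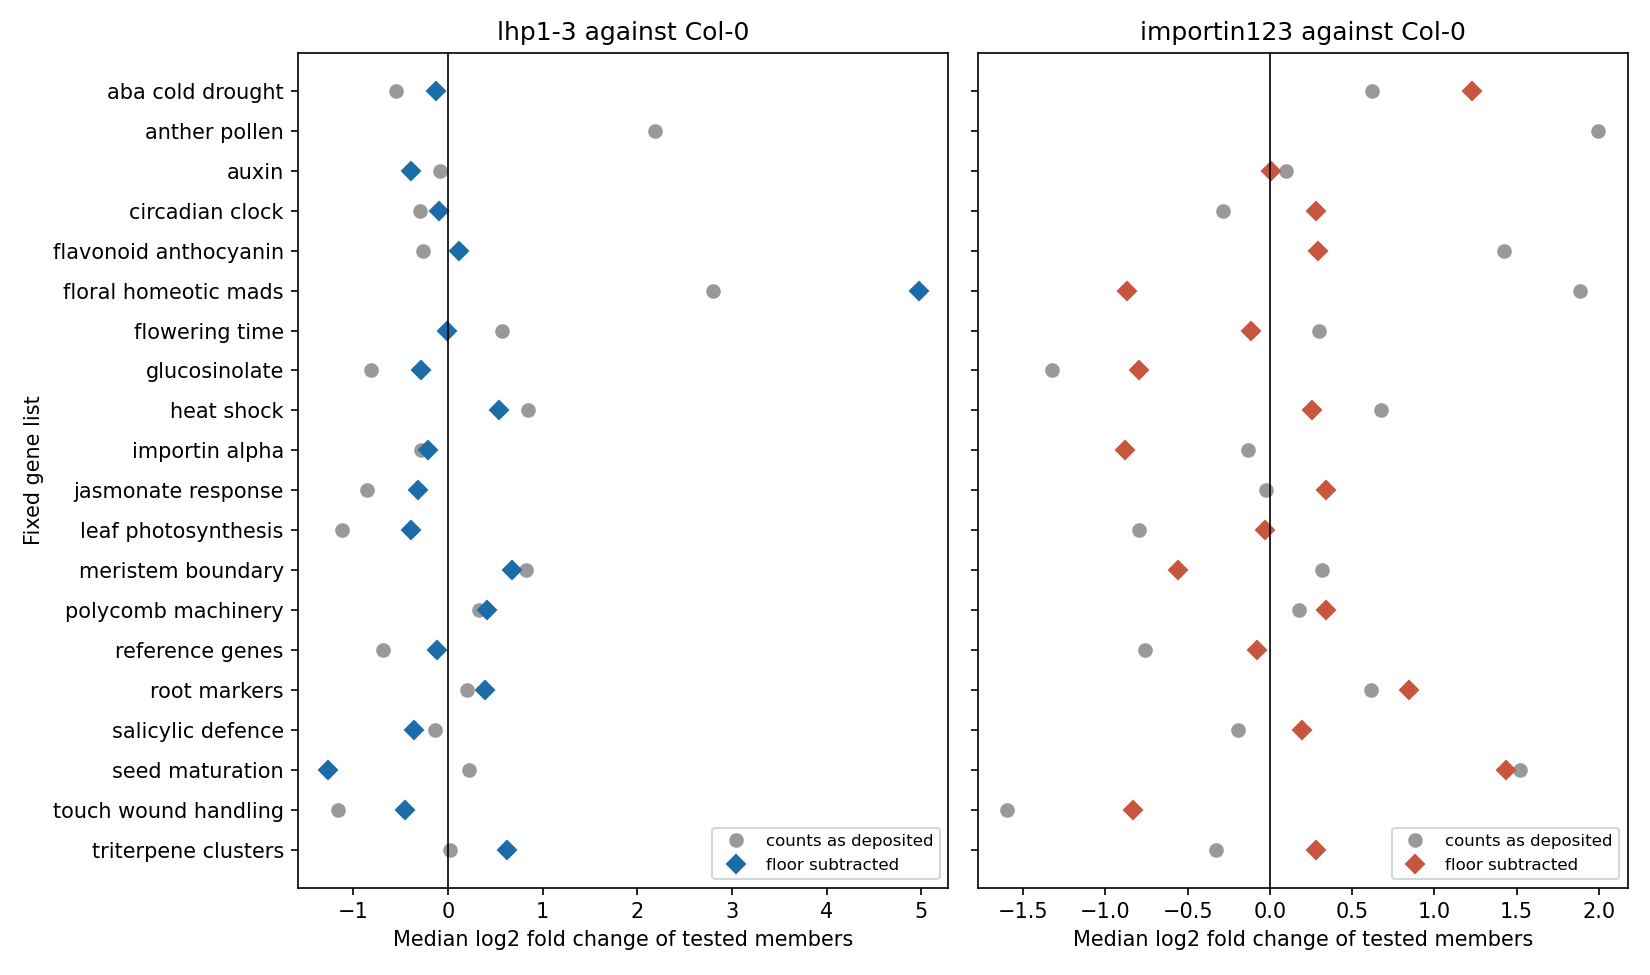
Median log2 fold change of the 20 fixed lists in each mutant against Col-0, on deposited and subtracted counts (anther and pollen genes deposited alone). Floral MADS-box medians in lhp1-3 were 2.79 and 4.97, the latter over 6 genes mostly kept for their level there. Seed maturation medians were 0.22 and -1.27.

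**Figure D3:**
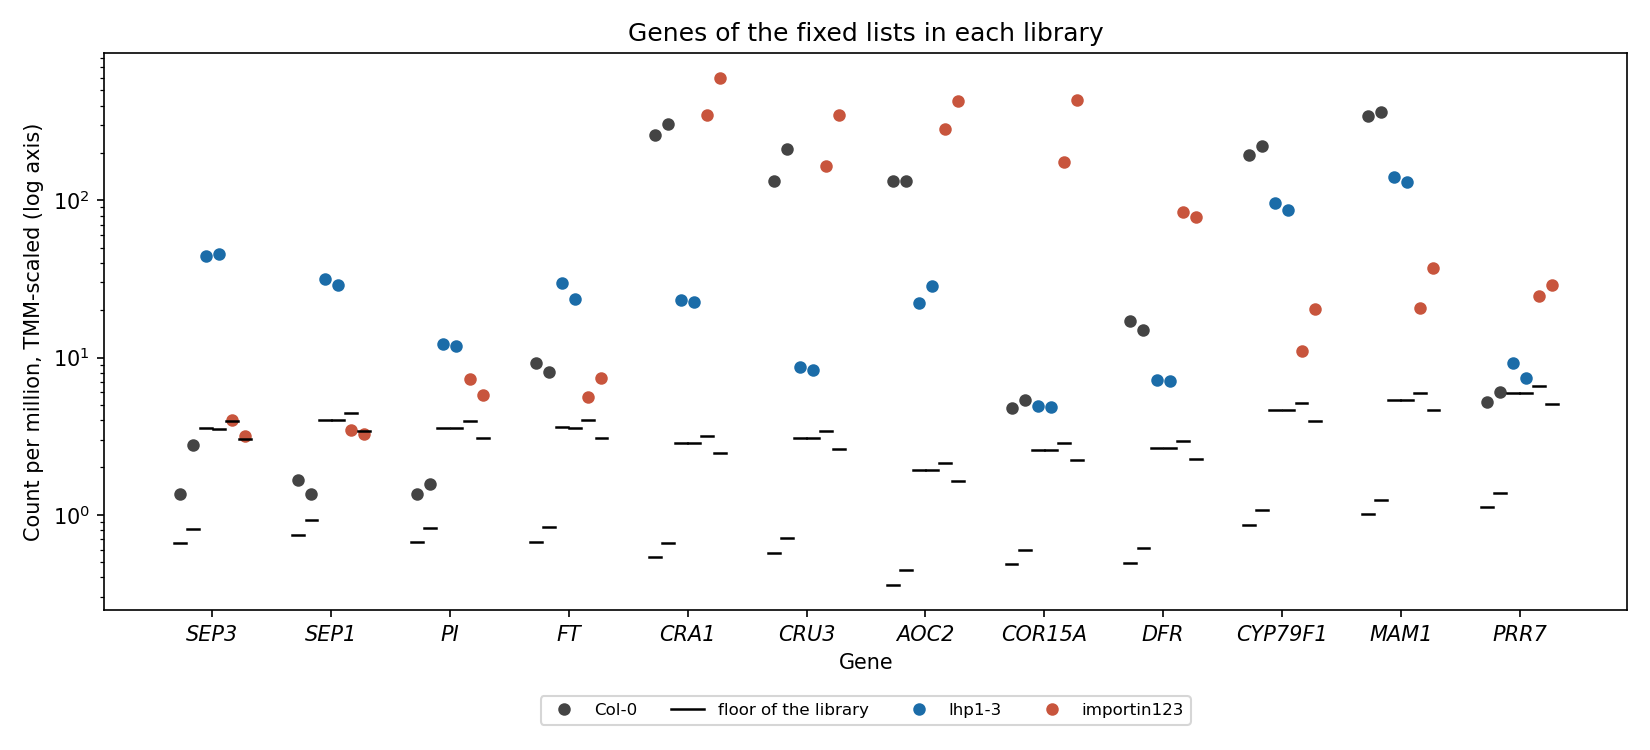
Level of 12 genes of the fixed lists in each of the 6 libraries, in CPM on a log axis, with ticks at the floor of each library. SEP3 stood at a mean of 44.9 CPM in lhp1-3 and 2.06 CPM in Col-0, and COR15A at a mean of 307 CPM in importin123.

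The question in the title was the overlap between the mutants. Genes lower in both with the largest falls were LBD32 (-3.46 ± 0.17 and -2.98 ± 0.19) and MIR5657 (AT5G04415, -2.44 ± 0.21 and -1.79 ± 0.24) in lhp1-3, against -2.92 ± 0.17 and -2.31 ± 0.19 for LBD32 and -2.66 ± 0.21 and -1.97 ± 0.25 for MIR5657 in importin123. RPL12-B, MRD1, MIR853 and HEI10 also fell in both, with deposited values of -3.70, -3.78, -2.73 and -2.56 in importin123. After subtraction the defensin gene PDF1.2 (AT5G44420, -1.57 ± 0.35) took the place of MIR5657, with -1.63 ± 0.35 as deposited in importin123. Genes higher in both with the largest rises as deposited were GRP16, LURE1.4, CYP705A32 (AT3G20950, 3.37 ± 0.30), AGL97 and LURE1.3 (AT5G43513, 3.33 ± 0.51) and GulLO1 (AT1G32300, 3.17 ± 0.30), at 3.61, 3.58, 3.48, 3.22, 3.18 and 3.14 in importin123, and none of these 6 could be tested after subtraction. After subtraction they were hda17, MIR5642b, LURE1.2, HSD7 (AT5G50690, 2.70 ± 0.24 and 3.69 ± 0.46), NHL22 (AT4G09590, 2.58 ± 0.34 and 3.66 ± 0.47) and PUM18 (AT5G60110, 2.61 ± 0.30 and 3.64 ± 0.46). In importin123 those other than hda17 stood at 3.92, 3.71, 3.95, 4.15 and 3.45 after subtraction. MRD1 and HEI10 are neighbours, and RPL12-B overlaps another annotated gene, so with strand not given in the sources used here their reads may be shared. PDF1.2 (-0.85) shifted as deposited in lhp1-3 without Col-0 replicate 2. LURE1.3 (2.57) shifted as deposited in lhp1-3 without lhp1-3 replicate 2. HSD7 (4.59) shifted after subtraction in lhp1-3 without Col-0 replicate 1. PUM18 (4.44) shifted after subtraction in lhp1-3 without Col-0 replicate 2. PDF1.2 (-1.50) lost the deposited call in importin123 without importin123 replicate 1. PDF1.2 (-0.91) and LURE1.4 (4.34) shifted as deposited in importin123 without Col-0 replicate 2. AGL97 (2.58 and 4.64) shifted as deposited in importin123 without Col-0 replicate 1 or 2. HSD7 (4.86) shifted after subtraction in importin123 without Col-0 replicate 1. PUM18 (4.25) shifted after subtraction in importin123 without Col-0 replicate 2. LURE1.2 (3.03 and 5.29) shifted after subtraction in importin123 without Col-0 replicate 1 or 2. MIR853 lost the subtracted call in lhp1-3 as given above. PDF1.2 lost the subtracted call in lhp1-3 without Col-0 replicate 2, lhp1-3 replicate 1 or 2 or importin123 replicate 1 or 2 (adjusted p = 0.0534 to 0.19). PDF1.2 lost the subtracted call in importin123 without Col-0 replicate 2 or importin123 replicate 1 or 2 (adjusted p = 0.0527 to 0.108).

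As deposited, 13164 genes were higher in both mutants and 9825 lower in both. Independent lists of these sizes would share 5998 and 3772 genes, and 20 simulated sets of unchanged groups with the same Col-0 libraries shared a mean of 1.3 and 0.9 genes, at most 5 and 4. After subtraction 1306 genes were higher in both and 916 lower in both, against 344 and 306 for independent lists and a mean of 0.4 and 0.2 in the simulations. One-sided Fisher's exact tests gave odds ratios of 204 and 94.1 as deposited and 16.9 and 8.26 after subtraction, with p = 2.30e-293 for the last and smaller, listed as 0, for the others. The 1306 genes made up 73.2% of those higher in lhp1-3 and 34.4% of those higher in importin123, and the 916 made up 65.1% and 21.4% of those lower. Neither reference holds both real effects and shared controls, and with 2 Col-0 libraries the controls could not be split into sets of 2, so part of the excess may come from the shared controls. Genes higher in lhp1-3 and lower in importin123 numbered 30 as deposited and 65 after subtraction, and 122 and 106 the other way. All had a called difference between the mutants. With the smaller floor the shared counts were 2803 and 1795, and with the larger one 942 and 502. After subtraction they were 435 and 171 without lhp1-3 replicate 1 and 728 and 313 without Col-0 replicate 2, and 463 genes were lower in both without lhp1-3 replicate 2. As deposited 6541 genes were lower in both without lhp1-3 replicate 1.

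Fold changes of the mutants against Col-0 were correlated across genes, which are not independent replicates. Pearson's r was 0.952 and Spearman's rho 0.946 over 33906 genes as deposited, and 0.614 and 0.594 over 19689 genes after subtraction. Simulated unchanged groups with the shared Col-0 libraries gave r of 0.521 and 0.491. The covariance was 1.79 as deposited against 0.0520 in the simulations, and 0.375 after subtraction against 0.0329, a difference of 0.342. With each mutant set against a different Col-0 library, r was 0.816 and 0.817 as deposited and 0.518 and 0.526 after subtraction. With the larger floor subtracted r was 0.474, and with the smaller one 0.791.

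**Figure D4:**
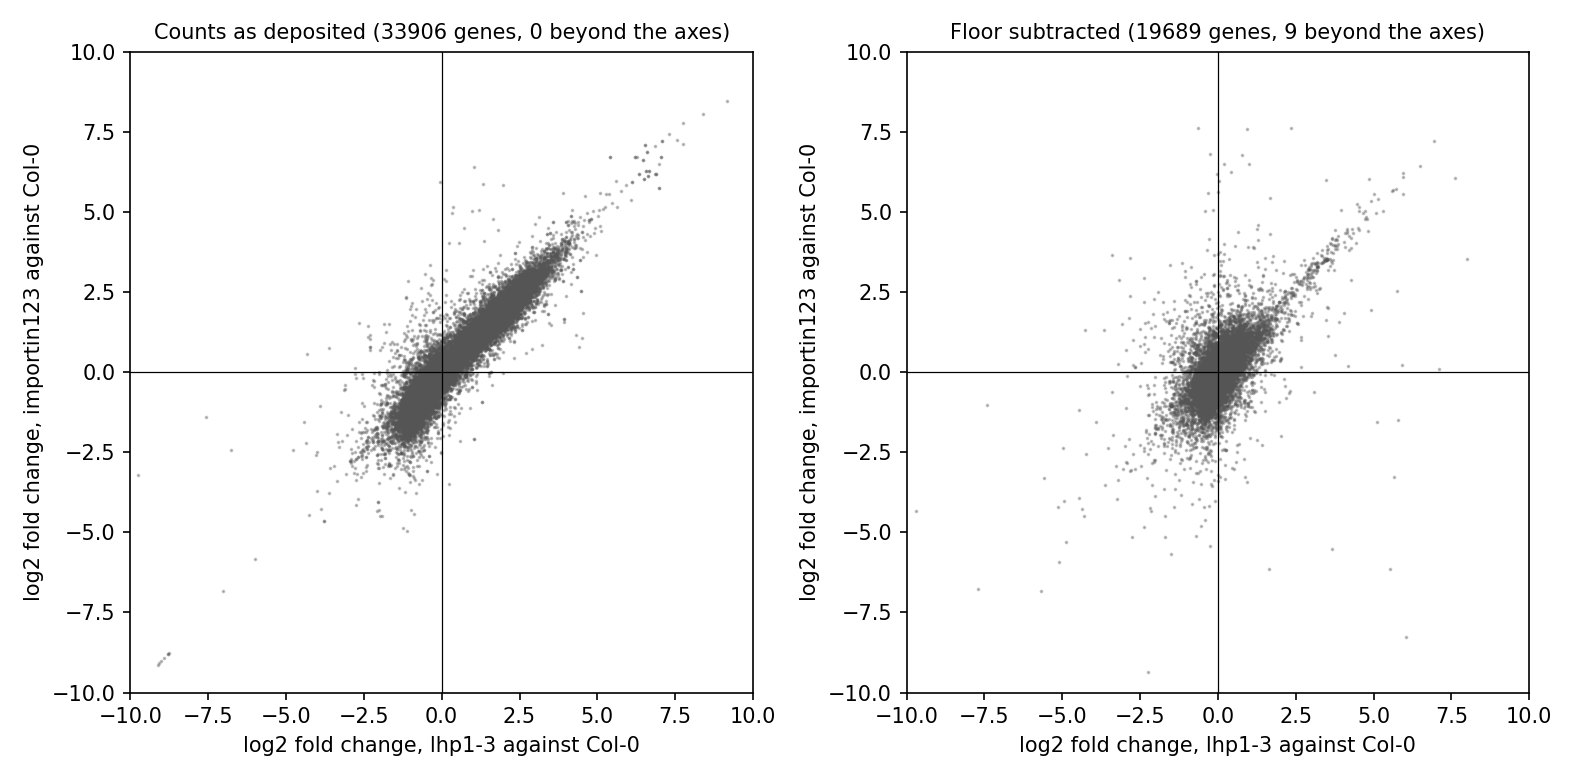
Log2 fold change against Col-0 of importin123 (vertical axis) and lhp1-3 (horizontal axis), 1 point per gene, as deposited (left) and after subtraction (right, with 9 genes beyond the axes). Pearson's r was 0.952 on the left and 0.614 on the right.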

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

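The tests of poly(A) selection, of release of silent genes, of scaling and of the shared floor were chosen after the results were seen, and the intron and shared Col-0 tests before. The intron test was later narrowed to protein-coding genes unlike organelle sequence, and snRNA added to the poly(A) test. Organelle features were kept in the deposited tests and left out after subtraction, and their share of counts stood above Col-0 in every mutant library. Chloroplast features took 14.9% and 14.5% of counts in lhp1-3 and 18.7% and 13.7% in importin123, against 2.95% and 3.27% in Col-0. Mitochondrial features took 0.463% and 0.467% in lhp1-3 and 0.639% and 0.457% in importin123, against 0.128% and 0.124% in Col-0. Genes called in opposite directions, all called between the mutants, numbered 30 and 122 as deposited and 65 and 106 after subtraction.

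The first pattern was the raised floor of silent genes in all 4 mutant libraries. Release of silent nuclear genes as its whole cause is argued against by mitochondrial features, whose median RPKM rose 6.69 to 9.34 times. The share of rRNA, snoRNA and snRNA was 0.684 times that of Col-0 (0.683 without snRNA, 0.865% against 1.27%, with the highest mutant library at 1.07% and the lowest Col-0 library at 1.24%). This does not settle weaker poly(A) selection, since the floor lowers other shares and organelle shares rose. Genomic DNA carried into the mutant libraries stays open: silent genes mostly made of intron stood at 0.808 to 0.830 times the RPKM of genes without introns (510 and 679 genes), just above the lower bound of 0.8 set before for DNA (0.813 to 0.836 over the genes first named), but Col-0 gave 0.829 and 0.838 and unspliced RNA would give the same. The reference genes moved with the floor, with a median log2 fold change in lhp1-3 of -0.69 as deposited and -0.11 after subtraction, as scaling factors pulled by the floor would give. Genotype and library preparation cannot be separated with these 6 libraries, and a biological source of organelle and silent reads was not tested.

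The second pattern was the correlation of the mutants' fold changes. Pearson's r fell from 0.952 to 0.614 after subtraction, so the shared floor may account for part of it, and a floor changed by 25% gave 0.791 and 0.474. Spread of the shared Col-0 libraries as the main cause is argued against by a simulated covariance of 0.0329 beside an observed 0.375 after subtraction (8.77%, near the bound of 10% set before). What remains could be a shared response, a preparation difference from Col-0 or an unremoved part of the floor, and its size depends on the floor assumed.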

How the results depend on the processing

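Floor subtraction, its variants, the RPKM minimum, nuclear genes alone and the crossed block were chosen after the data were seen. Counts below are higher and lower, for lhp1-3 and importin123 against Col-0, importin123 against lhp1-3, then both mutants.

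As deposited they were 14172 and 11368, 14351 and 11251, 962 and 2053, and 13164 and 9825, with r of 0.952 and 25 of 60 list tests called. The floor subtracted gave 1784 and 1408, 3797 and 4277, 1801 higher, 1306 and 916, and r of 0.614. With organelle-like genes kept it gave 1951 and 1238, 4016 and 4151, 1735 higher, 1446 and 798, and 0.649. A floor smaller by 25% gave 3607 and 2541, 5288 and 4931, 1630 higher, 2803 and 1795, and 0.791, and a larger one 1295 and 854, 3467 and 3621, 1824 higher, 942 and 502, and 0.474. Nuclear genes with a mean RPKM of at least 10 gave 763 and 623, 2041 and 2181, 589 and 444, 0.723 and 11 lists, from fewer genes tested. By construction these settings remove genes near the floor. limma-trend lowered the lower counts to 4231, 4764, 1219 and 2948, and r to 0.886, and the cause was not tested. The fit of only the 4 libraries compared raised the higher count between the mutants to 1451, without the Col-0 spread. On subtracted counts DESeq2 gave 2169 lower genes in lhp1-3 and 1403 lower in both, and the cause was not tested. A 2-fold minimum left 1898 and 3676 lower in the mutants and 316 and 391 between them, and after subtraction 775 and 395, 1367 and 1157, and 622 and 644. With each mutant against a different Col-0 library r was 0.816 and 0.817, and 0.518 and 0.526 after subtraction. With an estimated correlation 0 list tests passed on either set of counts (0 and 5 at an unadjusted p under 0.05), and fry called 25 and 17.

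RLE moved the median gene from 0.17 and 0.20 to -0.01 and 0.03 (log2), the higher share of calls from 55.5% and 56.1% to 49.3% and 50.1%, and the reference genes called lower from 11 and 9 to 11 and 10. Replicate numbers did not pair the libraries: replicate differences correlated across genes at -0.01 (Col-0 and lhp1-3), -0.10 (Col-0 and importin123) and 0.07 (the mutants), at -0.08, 0.03 and -0.06 after subtraction, and at -0.12, 0.01 and 0.04 over nuclear genes above 500 counts. With the replicate block the counts were 13858 and 11245, 14030 and 11171, 936 and 2081, and 12820 and 9753, and after subtraction 1485 and 1204, 3444 and 4013, 1485 and 2409, and 1123 and 796. The crossed block, tried first for lhp1-3 and then for importin123 after a second gene set, gave 14381 and 11231 in importin123, and 3711 and 4197 after subtraction.

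Leaving out 1 library, with the lone library assumed to vary like the others, gave 12411 to 14404 higher and 7489 to 10883 lower genes in lhp1-3, 12838 to 14547 and 8230 to 10920 in importin123, 456 to 1468 and 605 to 2664 between the mutants, 11637 to 12925 and 6541 to 9184 in both, r of 0.932 to 0.964 and 21 to 27 lists. After subtraction the ranges were 481 to 1698 and 266 to 1187, 2294 to 3818 and 2696 to 4100, 755 to 1902 and 1314 to 2590, 435 to 1290 and 171 to 704, and 0.567 to 0.682.

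Of 250 named values, called or not, the legacy test and no filter left all 250 on their side of the threshold, and the other fits of deposited counts 236 to 248 with none reversed, except limma-trend (229) and the RPKM minimum (107 of 122). Subtraction kept 205 of 226, the smaller floor 217 of 234 and the larger 170 of 207. These reversed in importin123 unless said. limma-trend gave IMPA6 0.34, FT 0.0856, IMPA9 0.34, LHP1 0.14 and AOS 0.49, and IMPA9 0.12 in lhp1-3. Subtraction gave IMPA4 0.11, SEP3 -3.29, SEP1 -8.26, LHP1 0.0440 and AOS 0.72, and with organelle-like genes kept 0.12, -3.27, -8.25, 0.0553 and 0.73. The smaller floor gave IMPA4 0.0086, SEP1 -0.49, LHP1 0.0214 and AOS 0.59, and the larger one IMPA4 0.20, SEP3 -8.99, SEP1 -7.66, LHP1 0.0527 and AOS 0.85, with IMPA4 0.0374 in lhp1-3. The RPKM minimum gave IMPA4 0.25 and AOS 0.76, and IMPA4 0.10 in lhp1-3. SEP1 and SEP3 lay at the floor there, so these values are not folds. The limma-trend values lacked the TMM factors, which shifts folds against Col-0 upward, but how far this made its reversals was not tested. The cause of the other reversals was not tested.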

Other observations

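The iron gene sets were chosen after the rises of bHLH38, bHLH39 and BHLH100 had been seen, from genes whose values had not, and the prediction was written before the test. All 10 iron deficiency genes rose in importin123 as deposited, and all 8 testable ones after subtraction (edgeR). They were BHLH101 (AT5G04150, 3.74), the ferric reductase gene FRO3 (AT1G23020, 2.80), ORG1 (AT5G53450, 2.74), the E3 ligase gene BTS (AT3G18290, 1.92), NAS4 (AT1G56430, 1.86), OPT3 (AT4G16370, 1.82), ZIF1 (AT5G13740, 1.77) and PYE (AT3G47640, 1.46). Values without 1 library are not given here, and BHLH101 had 4.86 and 2.27 CPM in Col-0. Of 6 iron storage genes 6 fell as deposited and 5 after subtraction, the ferritin genes FER1 (AT5G01600, -2.21), FER3 (AT3G56090, -0.83) and FER4 (AT2G40300, -2.73), and the vacuolar transporter genes VTL2 (AT1G76800, -1.40) and VTL5 (AT3G25190, -2.78), while VTL1 (AT1G21140) stood at -0.50 and did not pass. In lhp1-3 all 6 storage genes also fell as deposited (FER1 -1.44, VTL2 -0.63), and of the deficiency genes 6 fell and 2 rose, while after subtraction the medians were -0.42 and 0.03, and VTL5 alone passed, with -0.71.

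The third pattern was this joint change. An iron deficiency response in importin123 is a hypothesis, and medians of 1.89 for deficiency and -1.81 for storage genes met its prediction. Against lhp1-3, whose floor was similar, 8 of the 10 deficiency genes were higher and 5 of the 6 storage genes lower on either set of counts, with subtracted medians of 2.18 and -1.31, which argues against the floor shared by both mutants as its cause. MYB10 (0.45, adjusted p = 0.279) and MYB72 (0.11, adjusted p = 0.944) were not testable after subtraction and did not pass between the mutants as deposited. Whether iron uptake, sensing or supply differed was not tested.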
